A study of Drosophila melanogaster with 6 samples.

How the data were processed

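Chromatin from Oregon-R wild-type *Drosophila melanogaster* embryos aged 14 to 16 h was immunoprecipitated with the antibody NRO3 against ubiquitylated histone H2B (H2Bub) and sequenced. The labels name 3 ChIP samples and 3 input samples, and each input is assigned to the ChIP sample with the same replicate number. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the replicates came from separate embryo collections, so sign-flip p-values measure only the spread between these samples, which may be technical. The p-values from circular shifts and from bins rest on positions along the arms.

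The authors deposited 4 lists of significantly enriched regions, 1 for each ChIP replicate and 1 for the whole series. The series-wide list is called the combined list here. Only its file name ties it to a replicate set, and the libraries that entered it are not given in the sources used here. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Coordinates are on FlyBase genome release 5, per the file headers, and are printed counted from 1. The region caller, its threshold and the definition of the score are not given in the sources used here. No list was analysed here for the input samples.

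Each region carries a start, an end and a deposited score. The scores were examined for their scale. Within a list, 24.3%, 32.3% and 34.0% of the scores of replicates 1, 2 and 3 differed from that list's commonest score by the base-2 logarithm of a ratio of whole numbers with a denominator of up to 200, within a tolerance of 2e-09. For the natural and base-10 logarithms this share was at most 0.534% in these 3 lists. With the regions of replicate 3 split by width into 5 groups of equal size, the share was 66.0% in the narrowest group and 7.73% in the widest. A difference between scores of 1 list was therefore read as a difference of log2 ratios. Scores were compared within a list only, differences within a list were averaged over replicates, and no count was derived from them. Read depth is not given in the lists, so no counting interval can be attached to any region. The lists hold only regions that passed the authors' threshold, so bases outside them are uncalled and were not shown to lack the mark.

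The narrowest region was 1301 bp in each replicate list and 1001 bp in the combined list, so the minimum width differed between them. Regions within a list did not overlap. Covered shares were computed as bases inside regions divided by the sequence length in the file headers, for the 6 major arms (2L, 2R, 3L, 3R, 4 and X) unless stated otherwise. Means and standard deviations are over the 3 replicates.

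Agreement between lists was measured as the base-pair Jaccard index, the shared bases divided by the bases in either list. It was tested against 1000 circular shifts of 1 list along each arm, with a one-sided permutation p and Benjamini-Hochberg adjustment over the 3 pairs. The smallest p that these shifts can give is 0.001. A region counted as shared when it overlapped another by at least 1 bp, and chance shares of regions came from 200 shifts. X and the 4 large autosomal arms, and the 2 Mb nearest the centromere and the rest of the 5 large arms, were compared by an exact two-sided sign-flip permutation test over the 3 replicates. That test cannot go below 0.25. Bins of 500 kb were also permuted 100000 times between classes. Neighbouring bins are not independent replicates, so those p-values describe variation along the chromosomes. The tests of Jaccard indices, of X against autosomes and of the proximal windows, and the alternatives listed below, were fixed before the data were examined. Chosen after seeing the data were the sign-flip test of pairs of arms, the bin test of the proximal windows, the values without 3R and in 1 Mb steps, the split of regions by width with its midpoint measure and 200 joint shifts, and the correlation of bins between replicates. Alternatives added after seeing the data were lists brought to equal covered bases and combined regions of at least the replicate minimum width.

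Regions named in the text follow a rule fixed in advance, which takes the 5 longest and the 5 highest-scoring regions of the combined list on the major arms and the 5 longest stretches without a region in any replicate list. Other named regions and bins were chosen after their values were seen. The planned placement of regions in genes and the planned test of 24 gene lists were not run. The gene table at hand is on genome release 6, and coordinates of different releases cannot be mixed, so no gene is named.

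The alternatives were the 50% of regions with the higher scores, a minimum width of 1000 bp, merging of regions under 1000 bp apart, a 50% reciprocal overlap, random placement, other bin and window sizes, X without the proximal 2 Mb, all sequences, the combined list and leaving out each replicate. On simulated data, 1 of 20 pairs of independent lists passed a one-sided p of 0.05. The bin permutation passed 0.05 in 2 of 40 simulations with no shift and in 26 of 40 with a shift of 5 percentage points. The simulated regions were placed at random and the simulated bins were drawn independently of each other. These rates therefore do not show how the tests behave where coverage is clustered along the arms. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.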

Results

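H2Bub-enriched regions were mapped in late embryos of a wild-type strain, in 3 ChIP replicates that the labels each pair with an input of the same number. The series holds 1 stage, 1 genotype and 1 antibody. The comparisons it allows are therefore between replicates, between the replicate lists and the combined list, and between parts of the genome. The replicate lists held 5237, 5218 and 5428 regions, and the combined list held 5802. On the 6 major arms the replicate regions covered 29.2, 33.7 and 32.4 Mb. The median region was 3347 ± 236 bp wide (SD, n = 3). Read depth was unknown for all lists, since they give no counts. Nothing in the labels says that the replicates came from separate embryo collections, so sign-flip p-values measure the spread between these samples, while those from shifts and bins rest on positions along the arms.

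H2Bub regions occupied 26.4% of the major arms and little of the separate heterochromatic scaffolds. The 6 major arms were covered over 26.4% ± 1.93 of their bases (SD, n = 3). Arm 2R had the highest mean covered share, 29.0% ± 2.04, and the means were 27.0% ± 2.09 on 3R, 26.1% ± 2.15 on X, 25.3% ± 1.71 on 2L and 25.2% ± 1.78 on 3L (SD, n = 3 each). The order of 3R and X turned in the combined list, with 31.48% on 3R and 31.51% on X, and with the 50% of regions that scored higher, with 21.0% and 21.9%. Chromosome 4, which is small and largely heterochromatic, was covered over 18.1% ± 1.48 (SD, n = 3). The heterochromatic scaffolds were covered over 1.10% ± 0.0413 (SD, n = 3), and the ratio of the major arms to these scaffolds was 23.9 ± 1.13 (SD, n = 3).

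Differences between arms were smaller than the SD of the arm means for several pairs, and were steadier within replicates. Arm 2R exceeded 3R by 2.01 ± 0.0517 percentage points, 2L by 3.73 ± 0.394 and 3L by 3.80 ± 0.364 (SD of the within-replicate differences, n = 3). Each of these differences was positive in 3 of 3 replicates. Arm 3L exceeded chromosome 4 by 7.07 ± 1.49 points, again in 3 of 3. Arms 2L and 3L differed by 0.0707 ± 0.0861 points, within the spread between replicates. The exact two-sided sign-flip permutation test gave p = 0.25 for each of the 4 larger differences, the smallest value 3 replicates allow. The pairs and this test were chosen after the shares were seen.

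Among the heterochromatic scaffolds, XHet was covered over 2.49% ± 0.820, 2RHet over 1.60% ± 0.0628, 2LHet over 1.55% ± 0.358, 3LHet over 0.905% ± 0.0697 and 3RHet over 0.599% ± 0.136 (SD, n = 3 each). YHet held 1 region in replicate 1 and 0 regions in replicates 2 and 3. The unplaced sequence U was covered over 0.189% ± 0.0257 (SD, n = 3). Uextra held 0 regions in all 4 lists. How multiply mapping reads were treated is not given in the sources used here.

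**Figure D1:**
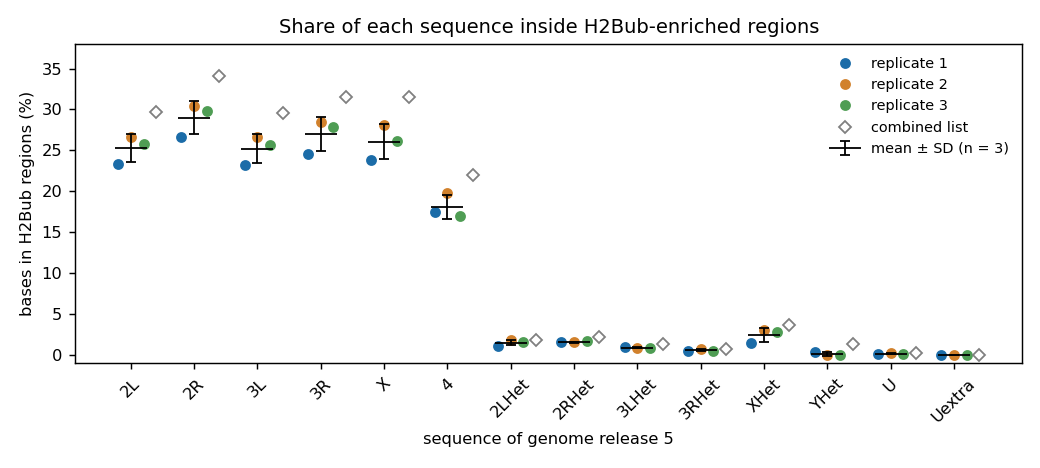
Share of the bases of each sequence that lay inside H2Bub regions (%), for each replicate (filled points), their mean ± SD (n = 3, black) and the combined list (open diamonds). The 5 large arms have means between 25.2% and 29.0%, chromosome 4 18.1%, and the Het scaffolds between 0.134% (YHet) and 2.49% (XHet).

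Most of the bases called in any replicate were called in all 3. Replicates 1 and 2 shared 28.1 Mb, replicates 1 and 3 shared 26.9 Mb and replicates 2 and 3 shared 29.8 Mb. Their Jaccard indices were 0.811, 0.775 and 0.822, where circular shifts of 1 list gave means of 0.150, 0.147 and 0.160 and no value above 0.223. Each pair had an adjusted one-sided permutation p of 0.001, the smallest 1000 shifts can give. Replicate 1 was the smallest list, and 96.5% of its bases lay in replicate 2 and 92.2% in replicate 3. In the other direction, 83.6% of the bases of replicate 2 and 82.9% of those of replicate 3 lay in replicate 1.

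Counted by region, 95.3% of replicate 1 regions overlapped a replicate 2 region and 81.6% of replicate 2 regions overlapped a replicate 1 region, against a mean of 41.0% of replicate 1 regions under shifts of replicate 2. Of the bases in at least 1 replicate list, 71.8% were in all 3 lists, 15.0% in 2 lists and 13.2% in 1 list. The bases in all 3 lists made up 22.0% of the major arms.

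The wider a region was, the more often its middle was called in both other replicates. The midpoint base lay in both other lists for 97.4% ± 1.52 of the regions of at least 20 kb, 91.7% ± 5.60 of those of 5 to 20 kb, 80.7% ± 9.43 of those of 2 to 5 kb and 40.4% ± 18.6 of those under 2 kb (SD, n = 3). Joint shifts of both other lists gave means of 23.5% to 23.6% in each of the 4 classes. Under 2 kb, the share was 61.5% in replicate 1 against 26.7% and 32.9% in replicates 2 and 3. Shifts gave means of 24.6%, 22.5% and 23.5% and maxima of 28.2%, 25.4% and 27.0% for these 3. The narrowest regions of replicate 2 were therefore little above chance. By an overlap of 1 bp, which wide regions meet more easily, 100%, 98.7% ± 0.789, 85.6% ± 7.78 and 45.8% ± 20.0 from the widest class to the narrowest overlapped both other lists, against 66.4%, 44.0%, 33.3% and 29.3% under shifts (SD, n = 3). The midpoint measure was added after seeing the data. The regions of at least 20 kb were 4.86% ± 0.683 of the regions and held 28.3% ± 2.12 of the covered bases (SD, n = 3).

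The combined list held the bases common to the replicates and added regions that were mostly narrow. It covered 37.4 Mb, or 31.1% of the major arms. It contained 100% of the bases called in all 3 replicates, 98.6% of those called in 2 and 73.2% of those called in 1. Of its own bases, 70.6% were in 3 replicate lists, 14.6% in 2, 9.54% in 1 and 5.29% in none. On the major arms, 3624 combined regions overlapped a region in all 3 replicates, and these had a median width of 5542 bp and a median score of 0.805. The 635 combined regions that overlapped none had a median width of 1284 bp and a median score of 0.365. Of these 635, 332 were narrower than 1301 bp, the smallest width found in any replicate list. Wide regions meet an overlap of 1 bp more easily and scored higher in every list. The widths and scores of these classes are therefore not independent of the overlap rule. On these arms, replicate 3 had 230 regions absent from the combined list, against 8 in replicate 1 and 33 in replicate 2.

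With all regions of each list, X and the autosomes did not differ in covered share beyond the spread between replicates. X was covered over 23.9%, 28.1% and 26.2% in replicates 1, 2 and 3, and the 4 large autosomal arms over 24.4%, 28.0% and 27.2%. The difference, X minus autosomes, was -0.559, 0.112 and -1.08 percentage points, with a mean of -0.508 ± 0.597 (SD, n = 3). The exact two-sided sign-flip permutation test over the 3 replicates gave p = 0.5, where 0.25 is the smallest possible. Over bins of 500 kb, 44 X bins averaged 26.3% ± 9.76 and 192 autosomal bins 26.6% ± 12.0 (SD over bins of the replicate means), with a two-sided permutation p of 0.88. The direction turned under 4 alternatives. Among them, the 50% of regions that scored higher gave X an excess of 1.26 ± 0.342 points (SD, n = 3). That excess was beyond the spread between replicates, with an exact sign-flip permutation p of 0.25, the smallest possible. The cut at the median score of the whole list keeps more X regions by construction, because X regions scored higher. This p is therefore no separate test of coverage on X.

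Coverage was low in the 2 Mb of the assembled arm nearest the centromere on 4 of the 5 large arms, and 3R was the exception. These windows stop at the end of each assembled arm and leave out the separate Het scaffolds. Of these, 3RHet was covered over 0.599% ± 0.136 (SD, n = 3). How multiply mapping reads were treated is not known here. No correction was made for bases to which reads cannot be assigned, so low coverage was not separated from poor mapping. The proximal 2 Mb of 3L (22543558 to 24543557) were covered over 3.99% ± 0.333, against 27.1% ± 1.91 on the rest of the arm. The proximal 2 Mb of X (20422828 to 22422827) were covered over 8.59% ± 1.87, against 27.8% ± 2.22. On 2R (1 to 2000000) the shares were 11.1% ± 1.23 and 30.9% ± 2.13, and on 2L (21011545 to 23011544) 11.8% ± 0.804 and 26.5% ± 1.79. On 3R (1 to 2000000) they were 26.8% ± 1.89 and 27.0% ± 2.11 (SD, n = 3 throughout). Within that 3R window, the 500 kb bin from 1.0 to 1.5 Mb was covered over 48.7% and the other bins over 12.9% to 23.0%. From 2.0 to 4.5 Mb, beyond the window, the 3R bins lay between 7.65% and 22.8%.

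Over the 5 arms together, the proximal windows were covered over 12.5% ± 1.10 and the rest over 27.8% ± 2.02, a difference of -15.3 ± 0.986 percentage points (SD, n = 3). It was negative in 3 of 3 replicates, with an exact sign-flip permutation p of 0.25, the smallest possible. Over bins of 500 kb, 19 proximal bins averaged 12.7% and 217 distal bins 27.8%, with a two-sided permutation p of 1e-05, the smallest that 100000 permutations give. That bin test was chosen after seeing the data. Its 19 proximal bins are neighbours within the windows of 5 arms, which the permutation ignores, so its p may be too small. Without 3R, the proximal windows were covered over 8.89% ± 0.926 and the rest over 28.0% ± 2.00 (SD, n = 3). In steps of 1 Mb from the centromeric end, coverage was 9.81% ± 0.732, 15.1% ± 1.47, 23.6% ± 2.06 and 30.3% ± 2.21 (SD, n = 3). From 4 to 10 Mb the steps lay between 20.7% and 30.5%.

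**Figure D2:**
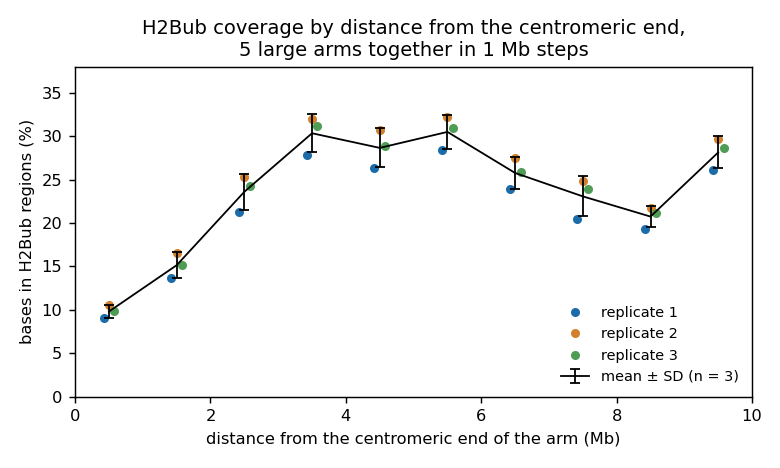
Bases inside H2Bub regions (%) in 1 Mb steps from the centromeric end, over 2L, 2R, 3L, 3R and X together, for each replicate (points) and as mean ± SD (n = 3, line). Coverage is 9.81% from 0 to 1 Mb and 30.3% from 3 to 4 Mb.

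Along the arms, coverage varied from bin to bin far more than between replicates. Across the 236 bins of 500 kb, which are not independent replicates, Pearson's r between replicates was 0.986, 0.981 and 0.988 for the pairs 1 and 2, 1 and 3, and 2 and 3. The bins with the highest and lowest share on each arm were picked after their values were seen. The highest of all bins was 61.4% ± 1.29 on 2R at 17.0 to 17.5 Mb, and the highest on 3R was 54.6% ± 2.32 at 19.5 to 20.0 Mb (SD, n = 3). The lowest bin of 3R, at 13.0 to 13.5 Mb, was covered over 5.06% ± 1.41 (SD, n = 3).

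**Figure D3:**
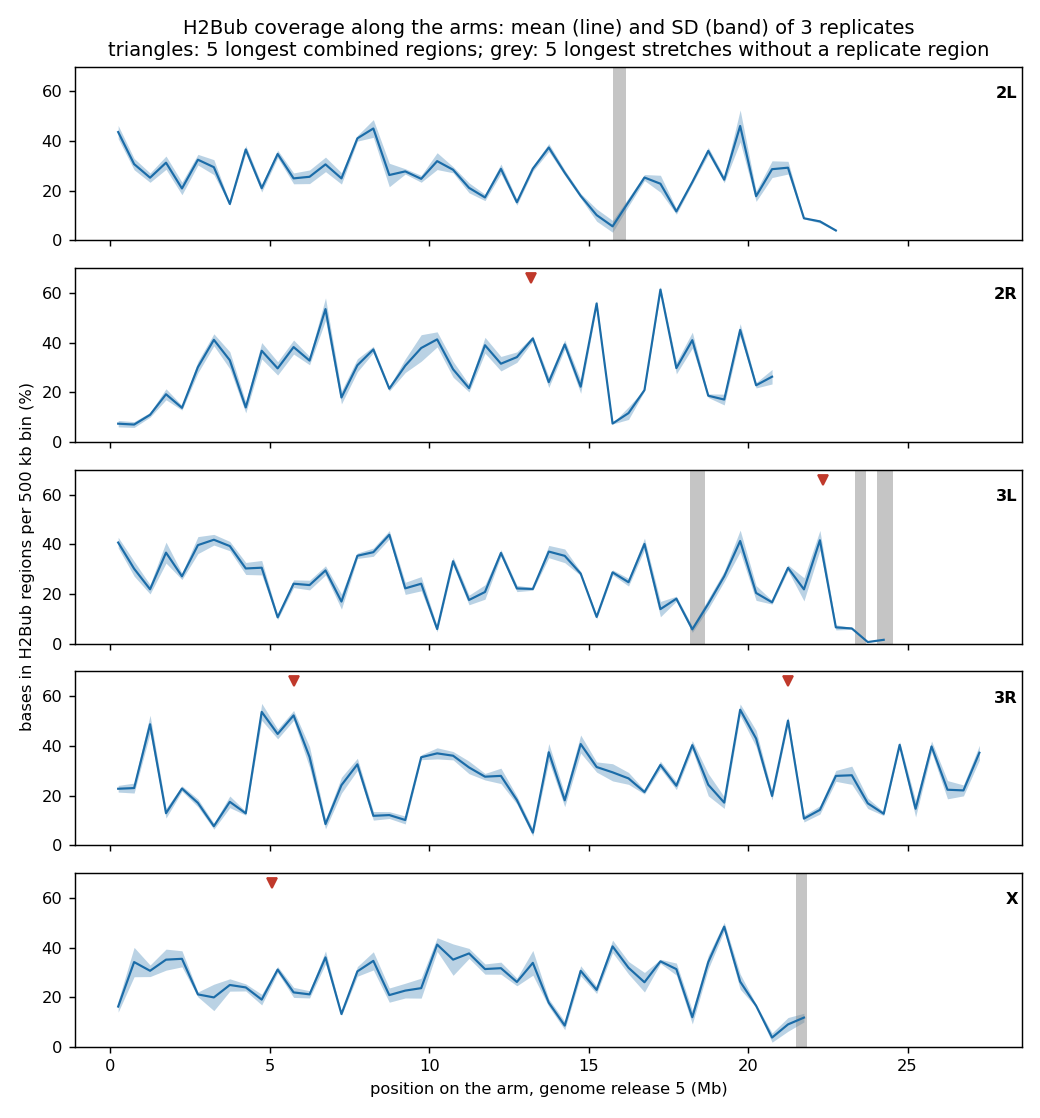
Bases inside H2Bub regions (%) in 500 kb bins along the 5 large arms, as the mean (line) and SD (band) of 3 replicates. Triangles mark the 5 longest combined regions and grey bars the 5 longest stretches without a replicate region. Bins range from 0.598% on 3L at 23.5 to 24.0 Mb to 61.4% on 2R at 17.0 to 17.5 Mb.

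The 5 longest combined regions were each over 100 kb wide and were called in all 3 replicates. They were X from 4997151 to 5119853 (123 kb), 3R from 21178883 to 21299214 (120.3 kb), 3R from 5699516 to 5816222 (117 kb), 3L from 22286910 to 22401701 (115 kb) and 2R from 13152190 to 13257840 (106 kb). Replicate regions covered 97.6% ± 1.57, 96.3% ± 1.96, 99.5% ± 0.391, 99.8% ± 0.135 and 98.3% ± 1.63 of them, in that order (SD, n = 3). The 3R region from 5699516 and the 3L region were a single region in every replicate. The X region was split into 9, 4 and 7 regions in replicates 1, 2 and 3.

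Of the 5 highest-scoring combined regions, 3 overlapped no replicate region. These were 3L from 9570289 to 9572284 and X from 4815836 to 4816836, both with a score of 3.06, and X from 22399249 to 22400249 with 2.91. They were 1996, 1001 and 1001 bp wide. The other two lay on 2R, from 15998189 to 16005716 with a score of 2.81 and from 15712774 to 15722035 with 2.77. Replicate regions covered 97.9% ± 1.61 and 90.5% ± 3.27 of them (SD, n = 3).

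The 5 longest stretches without a region in any replicate were 3L from 24029631 to 24529714 (500.1 kb), 3L from 18178855 to 18638586 (460 kb), 2L from 15768569 to 16167649 (399 kb), 3L from 23334957 to 23707420 (372 kb) and X from 21501834 to 21845931 (344 kb). The nearer edges of those at 24029631 and 23334957 on 3L and of the one on X were at most 0.836 Mb from the centromeric end. The nearer edges of those at 18178855 on 3L and on 2L were 5.91 and 6.84 Mb from it. The combined list covered at most 1.03% of any of the 5. Whether reads map poorly to these stretches was not examined.

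Wider regions had higher scores in every list. Spearman's rho between width and score across regions was 0.813, 0.814 and 0.800 in replicates 1, 2 and 3 and 0.808 in the combined list. Regions are not independent replicates, and no p was computed. With the regions of each list split by width into 5 equal groups, the median score was 0.489, 0.518 and 0.519 in the narrowest group of replicates 1, 2 and 3 and 1.08, 1.39 and 1.25 in the widest. The median widths of these groups were 1568 ± 48.5 and 12550 ± 1248 bp (SD, n = 3).

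**Figure D4:**
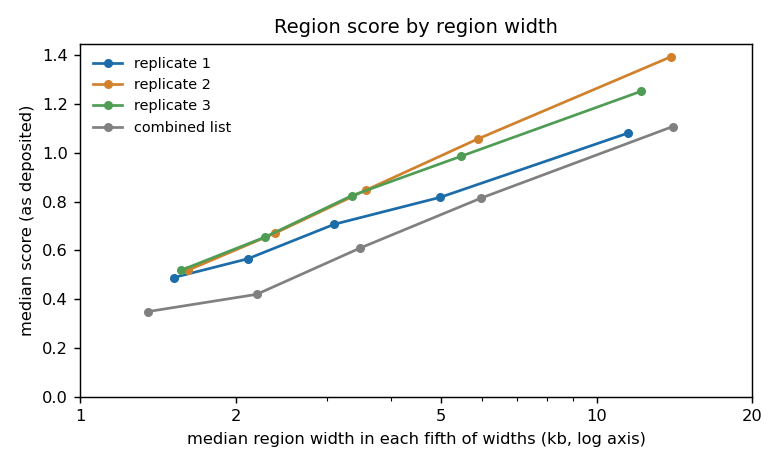
Median deposited score of the regions in each of 5 width groups, against the median width of that group (kb, log axis), for the 3 replicate lists and the combined list on the major arms. The score is higher in each wider group in all 4 lists.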

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

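The comparison shares from replicates 2 and 3 in the account of replicate 1 were chosen after its result was seen, the other tests of explanations were set before theirs, each pattern was noticed in the data it was tested on, and the length-matched scores outside the major arms were computed after regions there were seen. Region lists exist here for 1 group, so no biological explanation was tested.

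Sequences outside the 6 major arms, held regions in every list, a signal in data that the main comparisons leave out. The replicate lists held 47.3 ± 0.577 such regions (SD, n = 3), covering 121 ± 6.39 kb, and the combined list held 63. With widths split into 10 classes, the median score of regions on the Het scaffolds minus that of autosomal regions of the same class was -0.0445 ± 0.0181 (SD, n = 3). The 7, 9 and 8 regions on U in replicates 1, 2 and 3 scored higher than autosomal regions of their width, by 0.460 ± 0.108 on the deposited scale (SD, n = 3). Over all regions outside the major arms the length-matched difference was -0.0120 ± 0.0280 (SD, n = 3). How multiply mapping reads were treated on these sequences is not given in the sources used here.

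X regions scored higher than autosomal regions in all 3 replicates, while the covered shares of the full lists did not differ beyond the spread between replicates. The median score of X regions exceeded that of regions on the 4 large autosomal arms by 0.0842 ± 0.0147 (SD, n = 3), and by 0.0368 in the combined list. With scores read as log2 ratios, the replicate difference corresponds to 1.06-fold before the logarithm, and it is not a ratio of the scores. A difference in length is excluded as the cause, since the difference was 0.0841 ± 0.00983 between regions of the same width class (SD, n = 3) and 0.0536 in the combined list, while chromosome 4, also set against the large autosomal arms, gave -0.0572 ± 0.0403 (SD, n = 3). A higher detection threshold on X stays open: the shift was 0.0534 ± 0.0130 at the 90th percentile and 0.0836 ± 0.00693 at the 10th, between the outcomes set beforehand, while X had 44.1 regions per Mb against 43.5 on the autosomes. Noisier ratios in short X regions also stay open, with a shift of 0.0683 ± 0.00980 in the longest of 3 width classes and 0.0889 ± 0.00313 in the shortest.

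Replicate 1 covered 24.2% of the major arms, against 28.0% and 26.9% in replicates 2 and 3, although its 5190 regions there were not fewer than the 5170 of replicate 2. A higher detection limit in replicate 1 was not decided: of the 574 replicate 2 regions and 594 replicate 3 regions shared by those replicates and missing from replicate 1, 95.6% and 90.4% scored below the median of their own list, but so did 89.6% to 93.6% of the regions missing from replicate 2 or 3 alone. Narrower calls in replicate 1 were not decided either, since 63.9% and 59.6% of the bases it lacked lay inside replicate 2 and replicate 3 regions that overlapped one of its own, against 59.2% to 65.0% of the bases that replicate 2 or 3 lacked. Both outcomes set beforehand were met, but replicates 2 and 3 gave shares of the same size, so neither test bears on replicate 1 in particular. The counts did differ. Fewer regions were missing from replicate 2 alone, 110 replicate 1 regions and 93 replicate 3 regions. From replicate 3 alone, 309 replicate 1 regions and 253 replicate 2 regions were missing.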

How the results depend on the processing

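The equal-bases, replicate-minimum and centromere bin settings were chosen after seeing the data, and all others were planned. The alternatives run left the agreement between replicates and the low proximal coverage in place. The mean Jaccard index of 0.803 stayed between 0.775 and 0.822, with an adjusted permutation p of 0.001, under every alternative run. Proximal minus distal coverage ranged from -17.4 points with a 1 Mb window to -11.8 with a 3 Mb window, and was -19.1 over bins without 3R. The X comparison had no stable direction. From -0.508 points it turned to 1.26 with the 50% of regions that scored higher, which kept 58.8% of X and 48.1% of autosomal regions. It also turned to 0.375 in the combined list, to 0.0176 without the 2 Mb nearest the centromere, and to 0.583 with lists brought to equal covered bases, and it stayed between -0.819 and -0.223 without 1 replicate. The covered share of 26.4% became 20.7% with the 50% of regions that scored higher and 31.1% in the combined list, with a range of 25.6% to 27.4% without 1 replicate. A 50% reciprocal overlap lowered the mean share of regions shared between replicates from 87.6% to 69.7%, and that of combined regions found in a replicate list from 76.2% to 67.0%. Combined regions of at least the replicate minimum width raised the latter to 82.3%. By construction, a list with fewer regions covers less and a stricter overlap shares less. A cut at the median score of the whole list also keeps more of the X regions by construction, because X regions scored higher. The cause was not tested for the other changes. Pearson's r of log2 width and log2 score was 0.758, against a mean rho of 0.809, but a log of these scores depends on an unknown constant, so it tests nothing about that relation. The 1000 bp minimum width removed no region and so tested nothing. The genic location and gene list alternatives were not run, for want of an annotation on genome release 5. No paired analysis was possible because the groups that share replicate numbers are ChIP and input, and no input list was analysed here; the differences within replicates compare parts of the genome, not groups. Depth and the unknown treatment of multiply mapping reads limit what can be said of uncalled bases.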

Other observations

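The test of bordering regions was set before its result was seen, its repeat without the prompting regions was chosen after, and the 2R stretch and the tied regions were picked after their values were seen. Long stretches free of H2Bub regions made up a sizeable part of the arms. Across the 6 major arms, 164 stretches of at least 100 kb held no region in any replicate list. Together they spanned 26.2 Mb, or 21.8% of the arms. Stretches to which reads map poorly were not set apart. Several lay far from any centromere, such as 2R from 15721927 to 15998185 (276.3 kb), which begins 15.7 Mb from the centromeric end.

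That 2R stretch lies between the 2 regions with the highest scores among combined regions present in all 3 replicates, 15712774 to 15722035 with 2.77 and 15998189 to 16005716 with 2.81. A hypothesis drawn from it is that regions that border the 50 longest stretches without regions score higher than others of their length. The median length-matched score of such bordering regions was 0.0339 ± 0.0283 (SD, n = 3). It was 0.0621, 0.0341 and 0.00543 in replicates 1, 2 and 3, at the percentiles 100, 95.1 and 59.5 of 10000 random sets of as many regions. These sets include the 2 regions of each list beside the 2R stretch that prompted the hypothesis. Without them the medians were 0.0559, 0.0304 and -0.00470, at the percentiles 99.95, 92.7 and 39.1. The outcome set beforehand for the hypothesis, a median above 95% of the random sets in all 3 replicates, was then reached in replicate 1 alone. The outcome set against it was a median at or below that of the random sets in at least 1 replicate. Replicate 3 met that outcome without the prompting regions, though not with them. The hypothesis therefore did not hold in all 3 replicates.

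The top score of the combined list, 3.06, was shared by 3 regions, on 3L, X and U. They were 1996, 1001 and 1003 bp wide, and none overlapped a replicate region.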
